A study of Chlamydomonas reinhardtii with 48 samples.

How the data were processed

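The green alga Chlamydomonas reinhardtii, strain CC125, was exposed to 0, 10, 100 or 200 nM silver for 15 min, 1 h, 5 h or 16 h, and total RNA was labelled with Cy3 and hybridised to Agilent one-colour arrays, per the labels' protocols. Each of the 16 groups of dose and time held 3 arrays, 48 in all, and the labels name the arrays of a group as biological triplicates. Dose, time and replicate number were read from the sample titles.

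The authors deposited 1 scanner file per array, made with Agilent Feature Extraction 10.5.1.1 and its protocol GE1_105_Dec08, per the file headers. The deposited spot intensities are on a linear scale, and the headers hold that software's statistics of background subtraction and spatial detrending within each array. No scaling between arrays is recorded there. The intensities used were the processed signal, the median signal and the local background signal, together with the flags for spots that were outliers, saturated or well above background. The authors also deposited a table of log2 values for 15527 probes, whose column medians lay near 7.68 and whose scale, centring and filter are not given in the sources used here. Set against log2 of the processed signal, each column of that table correlated with its own scanner file at 0.962 or more, and 42 of the 48 columns correlated best with their own file. Of the other 6, the 3 columns of 200 nM at 15 min each matched a different array of the same group best, so replicate numbers there differ between the table and the scanner files. The remaining 3 matched an array of the same time and replicate number and of the neighbouring dose slightly better than their own. The slopes differed between columns, from 0.715 to 0.978, so the base of 2 rests on the range of values and the exact scale stays unknown. Direction needs no dye assignment on a one-colour array. No column of the table lacked a sample, and a table column was used only as an alternative.

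Control spots and outlier spots were left out and spots of a probe were averaged. The value of a probe was log2 of the processed signal minus the 75th percentile of that value on the same array. A probe was kept where it was well above background in all 3 arrays of at least 1 group, which left 14925 of 16283 probes, 1358 fewer. No spot was saturated. Group means were fitted with limma 3.58.1 (lmFit and eBayes, in R 4.3.3) over all 48 arrays, with 32 residual degrees of freedom, so that the 16 groups share 1 estimate of the spread for each probe, and p-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Each dose was compared with 0 nM at the same time in 12 comparisons. A moderated F test compared the 4 doses at each time, interaction terms compared the 200 nM effect between successive times, 200 nM was compared with 100 nM, and the 0 nM groups were compared between successive times. Design, named genes and alternatives were fixed before the data were examined, except where the text says otherwise. Figures were drawn with matplotlib 3.10.9.

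The array's transcript numbers come from an older gene model set. They were matched to the older locus tags in a RefSeq gene table of assembly Chlamydomonas_reinhardtii_v5.5, and 7107 of 16183 numbers matched, against 1491 to 1727 when the numbers were shifted by up to 5. In that table no symbol differs from the locus tag, and 9088 probes have no locus tag. The rule for named genes asked for a symbol or a description of function, and the locus tag was taken as the name once the table had been seen. The builds differ, so no coordinates are given and the table served for names and for gene order. The 24 gene lists fixed beforehand hold symbols, of which 0 were found in the table, so neither the lists nor the genes chosen by symbol are reported. For each comparison with calls, the genes named are the 10 with the largest rise and the 10 with the largest fall (5 each for 10 nM) among locus tags with an adjusted p under 0.05 whose 3 treated arrays all lay on the same side of the 3 control arrays. A locus tag was represented by its probe with the highest mean signal. Of the 41 locus tags with over 1 kept probe, 1 had all its probes called in a comparison, with the same sign. A probe that was not well above background in any array of a group has only a bound there, and its fold is then the mean of the bright group against, per array of the dim group, the higher of the lowest signal well above background and the probe's own signal.

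The share of spots well above background ranged from 70.3% to 94.8% between arrays with a median of 85.7%, and the 75th percentile of the processed signal ranged from 321 to 1671. The number of arrays limits the precision. The files place the arrays on 12 slides of 4, scanned on 2 days. On 6 slides, called complete here, each slide held the 4 doses of a single time and replicate, and the other 6, called mixed, held arrays of more than a single time or replicate. All comparisons were also made with the 24 arrays of the complete slides alone, an alternative chosen after seeing the slide layout and the spread between replicates. There 15 min and 1 h have 2 arrays per group and 5 h and 16 h have 1, whose spread is assumed to equal that of the other groups, with 8 residual degrees of freedom. All complete slides of a time were scanned on the same day, so dose comparisons at a given time on these slides lie within a scan day. Those of 15 min fell in scan 2 and those of 1 h, 5 h and 16 h in scan 1, so comparisons of 15 min with 1 h on these slides also compare the scans.

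The replicate numbers were checked by correlating deviations from the group means between same-numbered arrays. In 6 of 12 dose comparisons (100 nM at 15 min, 10 nM at 1 h and 5 h, and all doses at 16 h) every pair correlated over 0.1, so the numbers were taken to pair those arrays. In the other 6 they were not. At 16 h, and for 0 and 10 nM at 1 h and 5 h, the arrays of replicate 3 were scanned on another day than those of replicates 1 and 2. Scan or slide could therefore also give such correlations there. Alternatives were normexp background correction (offset 50) on the median and background signals, quantile normalization, the authors' table, no filter, blocks for replicate number within time, slide and scan day, a fit with only the 12 arrays of the same time, eBayes with trend and robust set, 1 probe per gene, and leaving out each array. The mean signal column named in the plan is not in the files as used here, so normexp ran on the median signal, and that setting changes both the signal and its background correction. The covariance that unchanged groups would give was also computed from residuals of a single time, unpaired and with same-numbered arrays paired, and that computation was tested on simulated data.

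The fitting function was tested on simulated data with the real means and residual SDs over 14396 probes, with 200 probes changed. For 200 nM against 0 nM at 1 h it recovered 46% of 4-fold and 1% of 2-fold changes with 48 arrays, and 69% and 17% with the complete slides. At 5 h it recovered 44% of 4-fold changes with 48 arrays and 28% with the complete slides.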

Results

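RNA of Chlamydomonas reinhardtii was measured at 4 silver doses and 4 exposure times with 3 arrays in each of 16 groups, to compare each dose with cells without silver at the same time. Values below are log2 signals relative to the 75th percentile of the array, as mean ± SD over 3 arrays, and changes are log2 fold changes with the standard error from limma. Arrays of a group correlated at a median of 0.966 over 14396 probes, with a lowest value of 0.828. On the complete slides alone the median was 0.985 over 8 pairs and the lowest 0.969. Of the 24 arrays on mixed slides, 0 were nearest to an array of their own group, against 8 of the 24 on complete slides, so values on the complete slides are given beside the counts and beside each named gene whose fold moved by over 1.5 times there. At 15 min and 1 h an array on a mixed slide has no other array of its group on such slides, which lowers its chance in that count. An array of the same time was nearest for 12 of the arrays on mixed slides and for 21 of those on complete slides. An array of the same slide was nearest for 22 of the arrays on mixed slides and for 11 of those on complete slides. Replicates 3 of 0 nM at 15 min, 1 h and 5 h correlated better with a 200 nM group of another time than with their own. The labels were kept in all fits.

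**Figure D1:**
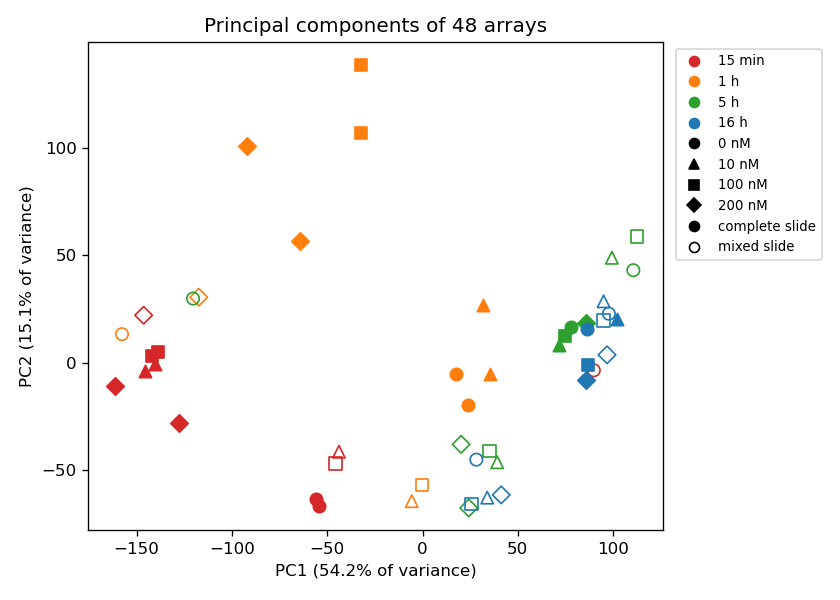
Principal components of the 48 arrays over probes measured on all of them, with PC1 (54.2% of variance) on the horizontal and PC2 (15.1%) on the vertical axis. Colour marks time, shape marks dose, filled symbols are complete slides and open symbols mixed slides, and at 15 min the filled 0 nM arrays lie at -56.0 and -54.5 on PC1 and the open one at 89.9.

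After 15 min of 200 nM silver, CHLRE_04g214800v5 rose from -3.14 ± 0.55 to 4.07 ± 0.46 (SD, n = 3), a change of 7.21 (SE 1.80, adjusted p = 0.0145) or 148-fold. CHLRE_01g016600v5 rose by 6.09, CHLRE_01g031450v5 by 5.90, CHLRE_16g685700v5 by 5.76, CHLRE_13g570751v5 by 5.68, CHLRE_12g544450v5 by 5.41, CHLRE_01g035750v5 by 5.23, CHLRE_13g591550v5 by 5.17 and CHLRE_03g200000v5 by 5.00. CHLRE_06g278265v5 rose by 6.38, on a probe whose name marks it as cross-hybridising, so that value is uncertain. CHLRE_06g284350v5 stood at 2.93 ± 0.49 without silver and fell by 4.93 (adjusted p = 0.0155), or 30.4-fold. CHLRE_03g172950v5 fell by 4.62, CHLRE_02g092900v5 by 4.39, CHLRE_03g205100v5 by 4.32, CHLRE_06g252200v5 by 4.26, CHLRE_12g558526v5 by 4.13, CHLRE_06g284100v5 by 4.12, CHLRE_02g109200v5 by 4.09 and CHLRE_04g222600v5 by 4.07, and CHLRE_16g669900v5 was 18.4-fold lower. CHLRE_12g558526v5 and CHLRE_02g109200v5 were well above background in 2 of 3 treated arrays and CHLRE_04g222600v5 in 1. On the complete slides the rises of CHLRE_13g570751v5 and CHLRE_03g200000v5 were 4.91 and 4.38. The changes there were -4.11 for CHLRE_06g284350v5, -3.86 for CHLRE_03g172950v5, -3.48 for CHLRE_02g092900v5, -3.66 for CHLRE_03g205100v5, -3.12 for CHLRE_12g558526v5, -3.25 for CHLRE_06g284100v5, -2.77 for CHLRE_02g109200v5 and -3.32 for CHLRE_04g222600v5. In all, 1000 probes were higher and 1481 lower in the 48 arrays, against 1744 and 2069 on the complete slides. Among locus tags, 1204 passed, 443 higher and 761 lower, and 1180 of them had no overlap between the groups, where 42.3% of all measured locus tags had none and chance gives 10%. With only the 12 arrays of that time in the fit, limma called 0 probes, and without replicate 3 of the 0 nM group or replicate 2 or 3 of the 200 nM group it also called 0. With normexp it called 888, of which 50.8% were higher against 40.3% here, with quantile normalization 4029, with the authors' values 3961, with a slide block 1844 and with a scan block 2815. Of the 20 genes named, 14 held with normexp, 14 with a slide block and 18 with a scan block.

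With 10 nM at 15 min, CHLRE_12g507900v5 rose by 3.52 (SE 0.95, adjusted p = 0.0423), CHLRE_16g692650v5 by 3.17, CHLRE_07g350750v5 by 3.11, CHLRE_13g569400v5 by 2.99 and CHLRE_01g012500v5 by 2.94. CHLRE_03g187150v5 fell from -1.83 ± 0.78 to -5.75 ± 2.85, a change of -3.92 (SE 0.79, adjusted p = 0.0263), with 1 of 3 treated arrays well above background. CHLRE_12g527500v5 fell by 3.85, CHLRE_02g109200v5 by 3.59, CHLRE_16g685050v5 by 3.56 and CHLRE_03g160450v5 by 3.55. CHLRE_12g527500v5 and CHLRE_03g160450v5 were well above background in 1 of 3 treated arrays, and CHLRE_12g507900v5 in 2 of 3 arrays of each group. On the complete slides the changes were 4.23 for CHLRE_12g507900v5, -5.11 for CHLRE_03g187150v5, -5.16 for CHLRE_12g527500v5, -4.19 for CHLRE_02g109200v5 and -4.94 for CHLRE_03g160450v5. The 48 arrays gave 79 probes higher and 432 lower, and the complete slides 2304 and 3194. Replicate 3 of 10 nM, on a mixed slide, lay at -43.8 on PC1, near the 0 nM arrays of the complete slides, and the other 10 nM arrays lay at -146 and -140. It correlated at 0.992 with the 0 nM group of the complete slides and at 0.886 with its own group there. Without replicate 3 of 10 nM the count was 3081, without replicate 2 of 0 nM it was 83, and without replicate 3 of 0 nM or replicate 1 or 2 of 10 nM it was 0. With only the arrays of that time or with normexp limma called 0 probes, with a slide block 1116, with a scan block 805 and with the authors' values 309. Of the 10 genes named, 0 held with normexp by limma, 6 with a slide block and 8 in the authors' table. The higher share of the calls was 15.5%, and 32.2% after quantile normalization and 44.0% in the authors' table. With 100 nM at 15 min limma called 0 probes, where 2661 had an unadjusted p under 0.05, and the complete slides gave 4501. Quantile normalization gave 2, and the authors' values and a scan block 1 each. Without replicate 3 of 100 nM, which lay at -45.7 on PC1 where the others lay at -139 and -142, the count was 1924. CHLRE_04g214800v5 there had changes of 4.71 (adjusted p = 0.204) over 48 arrays and 7.58 (adjusted p = 3.83e-08) on the complete slides.

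After 1 h of 200 nM, CHLRE_11g479600v5 rose from 1.11 ± 1.88 to 5.43 ± 0.63, a change of 4.33 (SE 0.98, adjusted p = 0.0152), and CHLRE_09g410750v5 rose by 4.32, CHLRE_12g551650v5 by 4.27, CHLRE_09g394325v5 by 3.93 and CHLRE_12g532050v5 by 3.90. CHLRE_14g617400v5 rose by 3.56, its near neighbour in tag number CHLRE_14g617450v5 by 3.34, CHLRE_13g585050v5 by 3.36 and CHLRE_16g690400v5 by 3.05. CHLRE_01g053150v5 rose by 3.40 on a cross-hybridising probe. CHLRE_12g541600v5 fell from 0.00 ± 0.22 to -5.24 ± 1.43, a change of -5.24 (SE 0.96, adjusted p = 0.00428), and CHLRE_16g653900v5 fell by 5.00, CHLRE_09g393506v5 by 4.87, CHLRE_16g652000v5 by 4.63 and CHLRE_13g584200v5 by 4.49. CHLRE_17g703700v5 fell by 4.04, CHLRE_09g416050v5 by 4.01, CHLRE_12g517150v5 by 3.99, CHLRE_06g296700v5 by 3.87 and CHLRE_12g483700v5 by 3.87. Without silver, CHLRE_12g551650v5, CHLRE_09g394325v5 and CHLRE_16g690400v5 were well above background in 1 of 3 arrays and CHLRE_12g532050v5 in 2, and with silver CHLRE_12g541600v5 in 1 and CHLRE_09g393506v5 in 2. The complete slides gave rises of 5.70 for CHLRE_11g479600v5, 5.63 for CHLRE_09g410750v5, 5.45 for CHLRE_12g551650v5, 5.47 for CHLRE_09g394325v5, 5.51 for CHLRE_12g532050v5, 4.66 for CHLRE_01g053150v5 and 3.81 for CHLRE_16g690400v5, and replicate 3 of 0 nM lay at 3.27 for CHLRE_11g479600v5. The falls there had changes of -3.96 for CHLRE_09g393506v5, -5.43 for CHLRE_16g652000v5 and -2.84 for CHLRE_06g296700v5. The 48 arrays gave 237 probes higher and 225 lower, and the complete slides 2874 and 2622. Leaving out replicate 1, 2 or 3 of 0 nM gave 77, 53 or 2378 calls, and leaving out replicate 2 or 3 of 200 nM gave 10 or 156. With normexp the count was 8, of which 100% were higher against 51.3% here, and 0 of the 20 genes named held by limma. Their changes there ran from 3.99 for CHLRE_11g479600v5 to 1.68 for CHLRE_16g690400v5 among the rises. Among the falls they ran from -3.60 for CHLRE_12g483700v5 to -2.08 for CHLRE_12g541600v5. With a slide block the count was 3000, with a scan block 973 and with only the arrays of that time 0. Without the filter CHLRE_09g394325v5 (adjusted p = 0.0523) and CHLRE_06g296700v5 (adjusted p = 0.0501) did not pass.

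**Figure D2:**
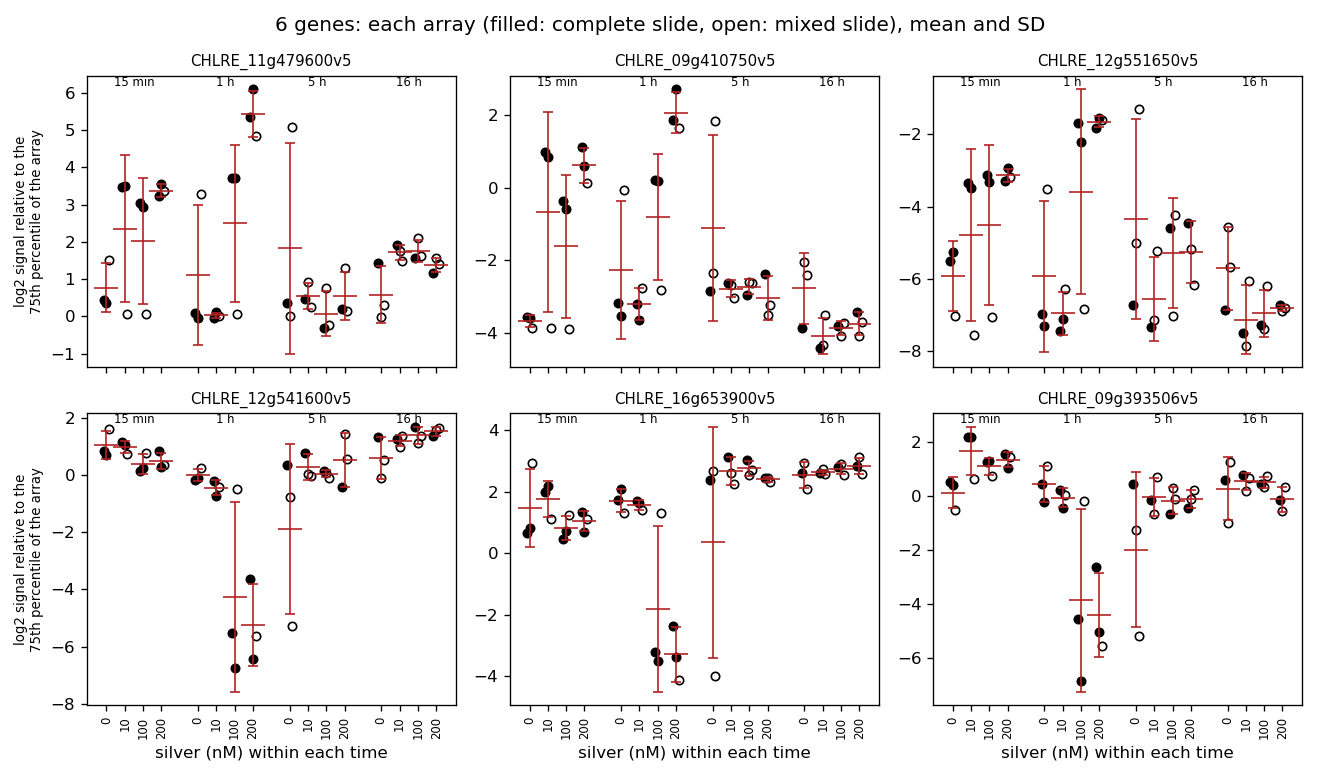
Signal of the 3 genes with the largest rise and the 3 with the largest fall at 200 nM and 1 h, in every array, by silver dose in nM within each time. Points are single arrays (filled on complete slides, open on mixed slides), and red marks are the mean and SD over 3 arrays. For CHLRE_12g541600v5 the 1 h arrays of 200 nM average -5.24 and those of 0 nM 0.00, and an open point of the 5 h 0 nM group lies at -5.28.

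With 100 nM at 1 h, CHLRE_17g722950v5 rose by 2.74 (SE 0.48, adjusted p = 0.0267) and CHLRE_07g320150v5 by 2.19 (SE 0.42, adjusted p = 0.0427), where CHLRE_17g722950v5 was well above background in 1 of 3 arrays without silver, and 3 probes were called in all. The complete slides gave 7238 calls, with CHLRE_17g722950v5 at 2.95 and CHLRE_07g320150v5 at 2.53. A slide block gave 2192 and a scan block 918, normexp 1 (lower) and quantile normalization 1 (higher), where 66.7% of the 3 were higher, and the authors' table and only the arrays of that time 0. Neither gene passed with normexp or in the authors' table, and CHLRE_07g320150v5 did not pass with quantile normalization (adjusted p = 0.0752). Without replicate 3 of 100 nM the count was 1963, without replicate 1 of 0 nM it was 82, and without each of the other 4 arrays in turn it was 0. With 10 nM at 1 h limma called 0 probes in the 48 arrays and 0 on the complete slides, where 115 and 387 had an unadjusted p under 0.05. CHLRE_12g541600v5 had a change of -0.43 there (adjusted p = 0.956). Between 200 and 100 nM, limma called 5 probes at 1 h (8 in the authors' table) and 0 at 15 min, 5 h and 16 h, where 168, 97 and 42 had an unadjusted p under 0.05, and the complete slides gave 3767 at 1 h and 0 at 15 min, where 2423 had an unadjusted p under 0.05.

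**Figure D3:**
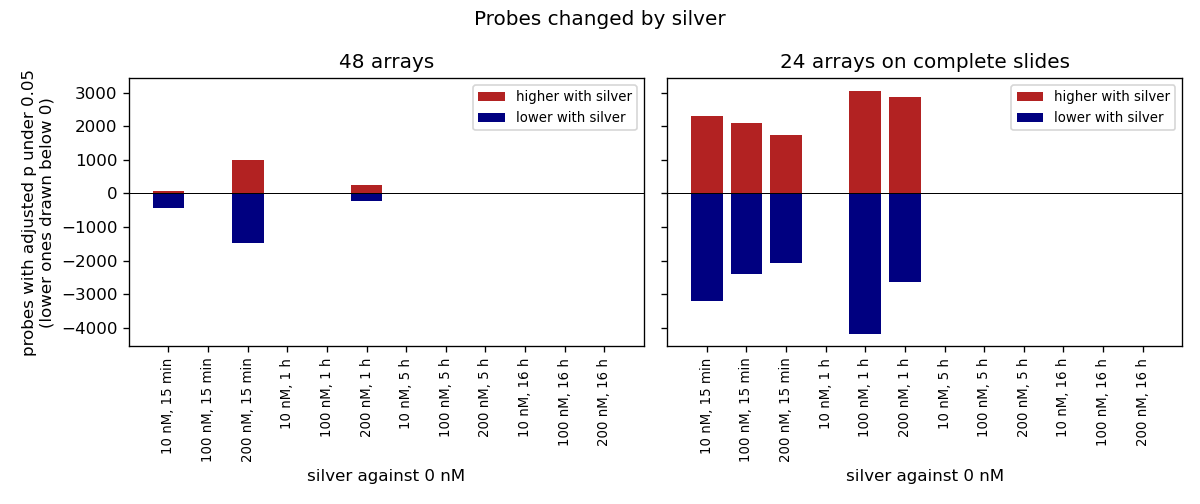
Probes with an adjusted p under 0.05 for each dose against 0 nM at each time, with higher probes above 0 and lower ones below, for the 48 arrays and for the 24 arrays on complete slides. At 15 min and 200 nM the bars stand at 1000 and 1481 in the 48 arrays and at 1744 and 2069 on the complete slides.

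At 5 h limma called 0 probes at 10, 100 and 200 nM, where 349, 191 and 282 probes had an unadjusted p under 0.05, and the complete slides gave 0, 6 and 5 and a slide block 3, 4 and 1. CHLRE_14g617400v5, which passed at 1 h, had changes of -1.76 (adjusted p = 0.992) at 200 nM over 48 arrays and 0.97 (adjusted p = 0.903) on the complete slides. After 16 h, CHLRE_03g159581v5 rose by 3.77 (SE 0.70, adjusted p = 0.0312) at 100 nM. It did not pass with normexp (adjusted p = 0.110), quantile normalization (0.209), trend and robust set (0.0529) or a slide block (0.338). CHLRE_06g292600v5, not well above background in any 0 nM array, was at least 1.45-fold higher at 100 nM (adjusted p = 0.0312), and it passed at 200 nM (adjusted p = 0.0133), where 2 of 3 treated arrays were well above background, so no fold is given. With normexp its change at 100 nM was -0.015, and at both doses it did not pass with normexp, quantile normalization, the authors' table or a slide block, nor at 100 nM with trend and robust set. CHLRE_07g336800v5 fell by 2.48 (SE 0.37, adjusted p = 0.00135) at 200 nM, and had a change of -1.34 with normexp (adjusted p = 0.849). The complete slides hold 1 array per group at 16 h, with the spread taken from other groups. CHLRE_07g336800v5 had a change of -3.42 there and CHLRE_03g159581v5 of 3.17, and CHLRE_03g159581v5 and CHLRE_06g292600v5 did not pass. The calls named here come from the 48 arrays. These calls were 2 probes at 100 nM and 2 at 200 nM, with 0 by limma at 10 nM, where 437 had an unadjusted p under 0.05, and the complete slides gave 0, 7 and 1, where 508 had an unadjusted p under 0.05 at 100 nM. Normexp gave 0 at both doses, quantile normalization 0 and 1 (lower), trend and robust set 0 at 100 nM, the authors' values 1 at 10 and at 100 nM, and a slide block 3 at 10 nM and 1 at 100 nM. At 200 nM the authors' values gave 1 higher and 2 lower, where 50% of the calls here were higher. Without replicate 1 of 0 nM the counts were 23, 43 and 29 at 10, 100 and 200 nM, leaving out any other array gave 0 or 1 at 100 nM and 1 or 2 at 200 nM, and with only the arrays of that time 0 at each.

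The moderated F test over the 4 doses called 1 probe at 15 min, 1231 at 1 h, 0 at 5 h and 3 at 16 h, and on the complete slides 5362, 8320, 22 and 2. At 15 min it called 1030 with quantile normalization and 730 in the authors' table, and at 16 h 0 with quantile normalization. The 200 nM effect differed between 1 h and 15 min for 257 probes, between 5 h and 1 h for 482 and between 16 h and 5 h for 0 by limma, where 140 had an unadjusted p under 0.05, and the complete slides gave 1064, 2061 and 0, where 932 had an unadjusted p under 0.05 in the last. Quantile normalization gave 469 and 860 for the first contrasts, and the authors' values 773 for 5 h against 1 h. CHLRE_13g585050v5 was among the genes with a difference in both of the first contrasts, of 4.40 (adjusted p = 0.0239) and -4.55 (adjusted p = 0.0173), with 4.45 and -2.66 on the complete slides. Without silver, limma called 0 probes between 1 h and 15 min, 0 between 5 h and 1 h and 0 between 16 h and 5 h, where 866, 2156 and 361 had an unadjusted p under 0.05, and the complete slides gave 4511, 984 and 147. The complete slides of 15 min and 1 h also differ in scan, which bears on the 4511 and the 1064. The 0 counts without silver include replicates 3 of 15 min, 1 h and 5 h, on mixed slides. These arrays correlated at 0.889, 0.852 and 0.846 with their own group on the complete slides. The 0 counts therefore do not show that cells without silver stayed unchanged over time.

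Across probes, which are not independent replicates, fold changes at 15 min correlated at 0.905 between 10 and 100 nM, 0.921 between 10 and 200 nM and 0.951 between 100 and 200 nM. Unchanged groups that share the 0 nM arrays gave 0.499 in simulation. The covariances of 0.918, 1.26 and 1.17 exceeded the simulated 0.205 by 0.712, 1.05 and 0.968. At 1 h the correlations were 0.249, -0.385 and 0.654, and the covariances differed from the simulated value by -0.082, -0.420 and 0.301, while the correlations on the complete slides were 0.347, 0.107 and 0.811. Without replicate 1, 2 or 3 of 0 nM the correlation of 10 and 200 nM at 1 h was -0.0727, -0.159 or 0.179. That of 10 and 100 nM ranged from 0.0434 without replicate 3 of 100 nM to 0.538 without replicate 1 of 0 nM, with 0.471 without replicate 2 of 0 nM and 0.391 and 0.426 without replicates 1 and 2 of 100 nM. The simulated value takes arrays as unpaired with a spread pooled over all times. Against a value from the residuals of same-numbered arrays of the same time, chosen after seeing the data, the covariances differed by 0.512, 1.03 and 0.959 at 15 min and by -0.339, -0.516 and 0.0856 at 1 h. At 5 h they differed by 0.067, 0.039 and 0.0066 from the simulated value and by -0.0710, -0.0652 and -0.131 from that of same-numbered arrays, all less than the SD of 0.191, 0.142 and 0.155 on leaving out single arrays. At 16 h, where the numbers were taken to pair all doses, the differences were 0.047, 0.019 and 0.041 and 0.151, 0.132 and 0.150, with SDs of 0.0887, 0.0841 and 0.0812. The 3 shared control arrays are too few to split. With separate controls, the 200 nM changes at 15 min and 1 h correlated at 0.485, those at 1 h and 5 h at -0.696 and those at 5 h and 16 h at 0.272, and on the complete slides at 0.712, 0.067 and 0.145. Leaving out single arrays gave 0.202 (without replicate 1 of 0 nM at 1 h) to 0.743 (without replicate 3 of that group) for the first, with 0.256 without its replicate 2. It gave -0.790 to -0.0194 for the second, the latter without replicate 3 of 0 nM at 5 h, and -0.0398 to 0.455 for the third, without replicates 2 and 3 of 200 nM at 5 h. The third was 0.157 without replicate 1 of 0 nM at 5 h, and at 16 h 0.159 and 0.172 without replicates 1 and 2 of 0 nM and 0.0855 without replicate 3 of 200 nM.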

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

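The count of arrays nearest the group of their place and its mark of 75% were chosen after the similarity of arrays had been seen, all values on complete slides after the slide layout, the allowance for the spread of the signal difference after that difference, and the splits within replicate numbers after the other splits. The 200 nM effect differed between times by an interaction test for 257 probes (1 h against 15 min) and 482 probes (5 h against 1 h). For 1 h against 15 min the log2 differences were 4.28 for CHLRE_12g527500v5, 4.49 for CHLRE_02g109200v5, 3.94 for CHLRE_17g722950v5, 2.28 for CHLRE_07g320150v5, 4.40 for CHLRE_13g585050v5 and -6.09 for CHLRE_09g393506v5. For 5 h against 1 h they were -4.40 for CHLRE_13g569400v5, -3.55 for CHLRE_17g722950v5, -2.20 for CHLRE_07g320150v5, -5.60 for CHLRE_11g479600v5, -6.24 for CHLRE_09g410750v5, -5.76 for CHLRE_12g532050v5, -5.32 for CHLRE_14g617400v5, -4.83 for CHLRE_01g053150v5, -4.55 for CHLRE_13g585050v5, -5.07 for CHLRE_14g617450v5 and -3.97 for CHLRE_16g690400v5. They were 7.65 for CHLRE_12g541600v5, 7.04 for CHLRE_16g653900v5, 6.75 for CHLRE_09g393506v5, 6.16 for CHLRE_16g652000v5, 5.70 for CHLRE_13g584200v5, 5.67 for CHLRE_17g703700v5, 6.23 for CHLRE_09g416050v5, 5.80 for CHLRE_12g517150v5, 5.74 for CHLRE_06g296700v5 and 5.73 for CHLRE_12g483700v5. Most genes listed for 5 h against 1 h were named for their 200 nM change at 1 h in the same arrays. That change is a term of the difference, so its size and sign give no separate support. Replicate 3 of 0 nM at 5 h, on a mixed slide, lay at -5.28, -3.97 and -5.18 for CHLRE_12g541600v5, CHLRE_16g653900v5 and CHLRE_09g393506v5, below the other 0 nM arrays of that time. For CHLRE_11g479600v5 and CHLRE_09g410750v5 it lay above them, at 5.10 and 1.82, and it correlated at 0.997 with replicate 3 of 200 nM at 1 h. Differences that moved by over 1.5 times on the complete slides were all smaller there. For 5 h against 1 h they were 4.13 for CHLRE_12g541600v5, 4.85 for CHLRE_16g653900v5, 4.54 for CHLRE_16g652000v5, 4.50 for CHLRE_13g584200v5, 3.56 for CHLRE_17g703700v5, 4.35 for CHLRE_09g416050v5, 4.50 for CHLRE_12g517150v5 and 4.09 for CHLRE_12g483700v5. They were -5.16 for CHLRE_09g410750v5, -3.08 for CHLRE_14g617400v5, -2.66 for CHLRE_13g585050v5, -2.42 for CHLRE_14g617450v5 and -3.08 for CHLRE_16g690400v5. There CHLRE_17g722950v5 (-1.57, adjusted p = 0.202), CHLRE_09g393506v5 (3.07, adjusted p = 0.126) and CHLRE_06g296700v5 (1.45, adjusted p = 0.457) did not pass. For 1 h against 15 min, where the complete slides also differ in scan, CHLRE_02g109200v5 had 1.99, CHLRE_12g527500v5 2.82, CHLRE_17g722950v5 3.08, CHLRE_07g320150v5 1.32 and CHLRE_09g393506v5 -4.81.

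Arrays on the 6 mixed slides stood apart from arrays with the same label, as in CHLRE_12g541600v5, where replicate 3 of 0 nM at 5 h lay at -5.28 and the others of its group at 0.37 and -0.75. A scan block left the median residual SD over probes at 0.532, against 0.340 on the complete slides, and the share of spots well above background was 2.68 points higher on the mixed slides (permutation p = 0.124), which argues against scan day and weaker signal as the whole cause. A slide block brought the SD to 0.424, between the bounds set for it, so a slide effect stays open. If each mixed slide had the dose order of the complete slides, 21 arrays would carry another label, and 14 of these (66.7%) correlated better with the complete-slide profile of that group, short of the 75% set as the mark, with a median correlation of 0.976 against 0.964 for the label, and that order ranked 1 of the 24 possible dose orders. Of the 8 arrays placed at 15 min or 1 h, 6 were closer to the group of their place. Replicate 2 of 200 nM at 5 h sits on a slide of 16 h arrays, and the labels that follow it in order each sit 1 place early. Arrays whose place names another time were all closer to it. Replicates 3 of 0 nM at 15 min, 1 h and 5 h have the places of 200 nM at 16 h, 15 min and 1 h. They correlated at 0.988, 0.989 and 0.966 with those groups and at 0.889, 0.852 and 0.846 with their label. These profiles come from other slides, which argues against a slide effect alone for these arrays. A match of arrays labelled 0 nM with the 200 nM group that their place names also argues against cultures that differed, for these arrays. Several others compare neighbouring doses at 5 h or 16 h, where both values lay close. Replicate 3 of 100 nM at 15 min was close to neither its label (0.910) nor its place (0.885) and correlated at 0.993 with replicate 2 of 0 nM at 15 min. Wrong labels may therefore account for part of the pattern, beside a slide effect. Outside those replicates 3 of 0 nM, wrong labels cannot be told apart from cultures that differed, which was not tested.

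At 10 nM, probes such as CHLRE_03g187150v5 were called at 15 min and 0 by limma at 1 h (115 at an unadjusted p under 0.05), and on the complete slides the 10 nM effect differed between these times for 3460 probes (0 by limma in the 48 arrays, 4000 at an unadjusted p under 0.05). Changes at 10 nM on the complete slides correlated at 0.0418 over probes between the times, which argues against a position effect, since position goes with dose on those slides. From 15 min to 1 h on the complete slides, 9717 probes changed at 10 nM against 4511 at 0 nM. These counts cannot decide whether 0 nM arrays that stand apart at 15 min are the cause. Such arrays would give the same order of counts if they lay nearer to 1 h than the 10 nM arrays. At 15 min the 0 nM arrays there lay at -56.0 and -54.5 on PC1 and the 10 nM arrays at -146 and -140. The remaining 0 nM array of 15 min, at 89.9, is on a mixed slide and outside this test. The times of 15 min and 1 h also differ in scan on the complete slides, which both doses share. The change at 10 nM and 15 min on the complete slides rests on 2 arrays per group, and replicate 3 did not share it. That array correlated at 0.992 with the 0 nM group and at 0.886 with its own. The array at the 10 nM place of that slide, replicate 3 of 100 nM, correlated at 0.885 with the 10 nM group. A response at 10 nM limited to the first minutes was not tested.

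Few probes were called at 5 h and 16 h, where CHLRE_07g336800v5 had the lowest adjusted p by limma among the genes named, in the 48 arrays. With only the arrays of that time in the fit limma called 0 probes at 200 nM and 5 h (282 at an unadjusted p under 0.05 with 48 arrays). That fit called 0 in all 12 dose comparisons, so the bound set for this test was wrong. The covariance expected of unchanged groups, which grows with the residual spread, was 0.244 from 5 h alone and 0.205 pooled over all times. This argues against a spread borrowed from other times at 5 h. From 16 h alone it was 0.133, so a borrowed spread stays open at 16 h. The share of spots well above background was 4.01 points lower at these times (a difference of -4.01, SE 1.65, two-sided permutation p = 0.0194), within its spread of the bound of 5 points. The permutation shuffled single arrays without regard to slide or scan day. Most arrays of 15 min fell in scan 2 and most of 16 h in scan 1. Group means of the 75th percentile of the signal were 793 to 902 at 5 h and 916 to 1383 at 16 h. They were 445 to 783 at 15 min and 610 to 1169 at 1 h. The later values lay within or above the earlier ones, which argues against weaker signal over all spots. A lower share of spots above background may still contribute, but it cannot be told apart from scan day here. Simulated 4-fold changes at 5 h were recovered at 44%, and 2-fold changes at 3%.

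For comparisons of 3 against 3 arrays, 10 splits exist, too few for a share under 0.05. The real and highest other counts were 511 and 1020 for 10 nM at 15 min (2 splits as large), 2481 and 0 for 200 nM at 15 min (1 split), 3 and 3440 for 100 nM at 1 h (3 splits), 462 and 852 for 200 nM at 1 h (2 splits), 2 and 0 for 100 and for 200 nM at 16 h (1 split each) and 5 and 64 for 200 against 100 nM at 1 h (2 splits). The other comparisons of that size had a real count of 0, which all 10 splits reach, with highest others of 56 for 100 nM at 15 min, 66 for 10 nM at 5 h, 2 for 200 nM at 5 h, 2774, 4705 and 10 for the successive times at 0 nM, and 0 elsewhere. The split with 3440 calls exchanged the replicate 3 arrays of 0 and 100 nM, both on mixed slides, and points to a structure of the arrays, where the complete slides gave 7238 and a slide block 2192. The splits with 1020, 56 and 2774 calls also exchanged the replicate 3 arrays of their groups, all on mixed slides. The split with 852 exchanged replicate 3 of 0 nM with replicate 1 of 200 nM. The split with 4705 exchanged replicate 1 of 0 nM at 1 h with replicate 3 of 0 nM at 5 h. Each of these also moved a replicate 3 array of 0 nM on a mixed slide. Over the 14396 probes measured on all arrays, 100 splits gave as many interaction calls as the real 256 in 5 (highest other 5092), as the real 481 in 10 (6291) and as the real 0 in 100 (2338), so chance is not excluded. For the F test the real counts of 1, 1263 and 0 at 15 min, 1 h and 5 h were reached by 22, 9 and 100 splits (highest others 2830, 3782 and 88), and the 3 at 16 h by 2 (highest other 4). The replicate numbers were taken to pair the arrays at 16 h, and of 100 splits that exchanged doses only within a number, 4 gave as many as 3 (highest other 3). Both shares are under 0.05, the second by 1 split. They rest on 100 random splits each, and no other interaction or F test had such a share, without correction for the number of tests. Chance is therefore not excluded for these 3 probes, and quantile normalization called 0. In the 6 paired comparisons the 4 such splits are too few for a share under 0.05, with real and highest other counts of 0 and 56 for 100 nM at 15 min, 2 and 0 for 100 and 200 nM at 16 h, and 0 and 0 for the others.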

How the results depend on the processing

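The complete slides, with and without a slide block, and the no-change covariances from a single time were chosen after seeing the data, and the other alternatives before the data were examined. Counts are of probes called by limma, and the cause of a change was not tested unless stated.

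With normexp the counts were 0 for 10 nM and 888 for 200 nM at 15 min, 1 for 100 nM and 8 for 200 nM at 1 h, and 0 for 100 and 200 nM at 16 h. This setting also replaces the processed signal by the median signal, so its effect cannot be put down to normexp alone. There the median change of all probes was -0.20 against 0.23 at 200 nM and 15 min and 0.50 against 0.09 at 200 nM and 1 h, and CHLRE_06g292600v5 at 100 nM and 16 h had -0.0154. With quantile normalization they were 2 for 100 nM and 4029 for 200 nM at 15 min, 1 for 100 nM at 1 h, 0 for 100 nM and 1 for 200 nM at 16 h, 469 and 860 for the 200 nM effect (1 h against 15 min, 5 h against 1 h), and 1030 and 0 for the 4 doses at 15 min and 16 h. With the authors' table they were 309, 1 and 3961 for 10, 100 and 200 nM at 15 min, 0 for 100 nM at 1 h, 1 for 10 and for 100 nM at 16 h, 773 for the 200 nM effect at 5 h against 1 h, 8 for 200 against 100 nM at 1 h and 730 for the 4 doses at 15 min. With trend and robust set, 100 nM at 16 h had 0.

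With a slide block they were 1116 for 10 nM at 15 min, 2192 and 3000 for 100 and 200 nM at 1 h, 3, 4 and 1 for 10, 100 and 200 nM at 5 h, and 3 and 1 for 10 and 100 nM at 16 h. With a scan block they were 805 and 1 for 10 and 100 nM at 15 min and 918 and 973 for 100 and 200 nM at 1 h. With only the 12 arrays of the same time, which leave 8 residual degrees of freedom, all 12 dose comparisons had 0, and all 56 calls of named genes were lost.

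On the complete slides they were 5498, 4501 and 3813 for 10, 100 and 200 nM at 15 min, 7238 and 5496 for 100 and 200 nM at 1 h, 6 and 5 at 5 h, 1, 0 and 7 for 10, 100 and 200 nM at 16 h, 1064 and 2061 for the 200 nM effect, 3767 and 2 for 200 against 100 nM at 1 h and 16 h, 4511, 984 and 147 between successive times at 0 nM, and 5362, 8320 and 22 for the 4 doses at 15 min, 1 h and 5 h. With a slide block there they were 6446, 5496 and 4934 at 15 min, 8469 and 6648 for 100 and 200 nM at 1 h, 22 and 20 at 5 h, 6, 48 and 9 at 16 h, 1804 and 3212 for the 200 nM effect, 5, 5522 and 9 for 200 against 100 nM at 15 min, 1 h and 16 h, 5962, 2936 and 330 at 0 nM, and 6907, 10023, 78 and 58 for the 4 doses.

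The replicate number as a block within time gave 1611 for 10 nM and 4132 for 200 nM at 15 min, 162 for 100 nM at 1 h, 638 for the 200 nM effect at 1 h against 15 min, and 1530 and 1968 for the 4 doses at 15 min and 1 h. In the 6 comparisons taken as paired, the block moved no count by over 1.5 times, and it changed no other call of a named gene (56 of 56 held). Arrays all correlated best with their own number in 3 of 12 comparisons.

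Leaving out 1 array gave 0 to 3081, 0 to 1924 and 0 to 2877 for 10, 100 and 200 nM at 15 min, 0, 0 to 1963 and 10 to 2378 at 1 h, 0 at 5 h, and 0 to 23, 0 to 43 and 1 to 29 at 16 h. Of the 56 calls of named genes, 53 held on the complete slides, 52 with quantile normalization, 50 in the authors' table, 14 with normexp, 43 with a slide block, 54 with a scan block and 53 without the filter. With the spread of 5 h alone the covariance above the no-change value was -4.52e-05 for 10 and 200 nM and -0.0321 for 100 and 200 nM, and paired by number -0.0710, -0.0652 and -0.131 for 10 and 100, 10 and 200, and 100 and 200 nM. Over the 336 cases of a named call with 1 array of its comparison left out, 157 held and 179 were lost. The share of spots well above background, 70.3% on the dimmest array, limits what can be measured for weak genes. The 24 gene lists were not run, since 0 of their symbols were found.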

Other observations

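The tests in this part were planned before their results were seen, but on the complete slides, a subset chosen after seeing the slide layout. At 200 nM, 1345 probes were higher at both 15 min and 1 h on the complete slides, where independent lists would share 336, and 1205 were lower at both, against 364. Of the 2633 probes called at both times, 96.8% moved the same way, a relation that may mark a response shared by the early times. In the 48 arrays 45 probes were called at both times, of which 25 were higher at both and 4 lower at both, against 15.9 and 22.3 for independent lists, so the relation rests on the complete slides. CHLRE_14g617400v5 and CHLRE_14g617450v5 passed at both times on the complete slides, at 2.47 and 2.75 at 15 min and 4.05 and 3.64 at 1 h.

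Neighbouring locus tags moved together more than shuffled ones at 200 nM and 1 h on the complete slides. Over 2865 neighbouring pairs of 6549 named genes, the mean product of centred changes was 0.133 of the variance, the highest of 10000 shuffles was 0.0892, and p = 1e-04, the smallest these shuffles can give (permutation test, one-sided). Without the probes whose names mark them as cross-hybridising it was 0.130 over 2749 pairs. Tandem copies that share probe sequence without such a mark could also give a value like 0.133, which was not tested.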
